A study of Mus musculus with 22 samples.

How the data were processed

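Per the labels, poly-A RNA was isolated with a column kit, made into stranded libraries and sequenced. The authors mapped the reads to mm10 and computed FPKM with Cufflinks 2.0.2, as deposited; the aligner and the gene annotation are not given in the sources used here. The authors' deposited Cuffdiff tables hold their fold changes as log2 values, their p-values and their q-values, adjusted by the authors over their own tests. The confidence bounds of FPKM, in 44 columns, were not used here. Symbols turned into dates were restored by locus for 27 genes, 102 joined symbols were kept as given, and 23016 genes had a transcript length from GENCODE M21.

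The deposited table holds an FPKM value for each library, so the test named in the design for that case was used. log2(FPKM + 1) was fitted with limma 3.58.1 (trend and robust settings) in R 4.3.3, for genes at FPKM of at least 1 in at least 2 libraries. A single fit covered the 19 fibroblast libraries and 9425 genes, and a second fit covered all 22 libraries and 10371 genes for cardiomyocytes against fibroblasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The added 1 pulls the folds of low genes toward 0. The labels do not state whether libraries came from separate animals, so the p-values measure only the spread between these samples.

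Lists of 847 entries in all, comparisons, naming rules and most alternatives were fixed before the data were examined. Each list was tested with a two-sided Fisher's exact test on its calls, adjusted over lists and directions, and with camera, at its preset correlation and with an estimated correlation. Length and GC content were corrected by removing from each library a smooth trend (splines with 4 degrees of freedom) on both. Relative depth was estimated from the smallest FPKM steps of 913 low genes with a single transcript. The test was also run on simulated log2 values, drawn independently for each gene, with 200 changed genes. It recovered 49% of changes of 1 log2 unit and 91% of 2 log2 units for 3 day TAC against sham, 61% and 96% for 10 day TAC, 49% and 96% for MI, 65% and 93% for 4 day swim, and 63% and 94% for 10 day swim. It recovered 57% and 97% for sham, 64% and 94% for 10 day swim against TAC, 64% and 92% for 4 day swim against 3 day TAC, 56% and 96% for TAC over time, and 67% and 97% for swimming over time. False calls made up between 2.47% (10 day swim against TAC) and 8.19% (10 day TAC) of its calls. Every list that passed was tested again without each library of the groups compared.

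Genes were named by a rule. In the 5 comparisons with sham or sedentary that came first, in cardiomyocytes against fibroblasts and in 10 day swim against 10 day TAC, the 8 largest rises and 8 largest falls among called genes at FPKM of at least 5 in the higher group could be named, and 4 of each in the others. Up to 4 called members of each list past its threshold could be added. The genes Mt1, Mt2, Nqo1, Hmox1, Postn, Col1a1, Col3a1, Acta2, Timp1, Tcf21, Pdgfra, Myh6, Tnnt2, Ptprc and Pecam1 were named whatever their values. Joined symbols, predicted genes and small RNA genes were left out, except where a count of 5 or fewer was spelled out.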

Results

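Messenger RNA was sequenced from cardiac fibroblasts (CF) and cardiomyocytes (CM) of male wild-type C57BL/6 mice, 10 to 14 weeks old. The 19 fibroblast libraries fell into 7 groups: sedentary mice (n = 3), mice 3 days after a sham operation (n = 2), mice 3 days (n = 3) and 10 days (n = 3) after TAC, mice 5 days after MI (n = 2), and mice that swam for 4 days (n = 3) or 10 days (n = 3). TAC was read as transverse aortic constriction, which overloads the left ventricle with pressure, and MI as myocardial infarction; the labels give only the abbreviations. The 3 cardiomyocyte libraries came from sedentary mice (inferred for the wt library of each cell type). Expression was given as FPKM, fragments scaled by transcript length and library size, for 23359 genes. No read counts were given, so the absolute depth of each library is unknown. Total FPKM per library, in units of 1000, ranged from 85.1 to 119 in sedentary fibroblasts, 114 to 118 in sham, 157 to 169 after 3 days of TAC, 138 to 155 after 10 days of TAC, 100 to 101 after MI, 197 to 205 after 4 days and 148 to 159 after 10 days of swimming, and 180 to 198 in cardiomyocytes. Depth relative to the shallowest library ranged from 1.0 to 3.31. In simulated data with 200 changed genes the test recovered 49% to 67% of changes of 1 log2 unit and 91% to 97% of 2. Of its calls there, 2.47% to 8.19% were false (threshold 5%).

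The fibroblast libraries separated along a first axis that did not follow disease against exercise. The first principal component held 59.8% of the variance. It placed the sedentary, sham and MI libraries together (scores from -62.9 to -38.4), apart from the 3 and 10 day TAC libraries (17.2 to 51.9) and the 4 day swim libraries (24.5 to 62.3), with 2 of the 10 day swim libraries in between (-6.03 and 2.37) and the third (22.1) among the TAC libraries. The second component, with 13.9% of the variance, set the MI libraries (30.7 and 40.6) apart from the swim libraries (-24.2 to -16.8). Transcript length moved with the first axis. The 7 sedentary, sham and MI libraries had positive slopes of expression on length, the lowest being 0.147 log2 per doubling, while the 12 TAC and swim libraries had negative slopes, the highest being -0.0544. Rn45s, the 45S ribosomal RNA precursor, which poly-A selection should leave out, was listed at 215 ± 52.4 FPKM (SD, n = 3) in sedentary and 164 ± 25.9 (n = 2) in sham fibroblasts, against 2451 ± 764 (n = 3) and 3232 ± 3283 (n = 3) after 3 and 10 days of TAC, 915 ± 538 (n = 3) and 1234 ± 522 (n = 3) after 4 and 10 days of swimming, and 704 ± 827 (n = 2) after MI. With the trend on length and GC content removed, the first component held 49.4% of the variance and the MI libraries again lay at negative scores (-27.3 and -21.3) with the sedentary and sham libraries. For the genes called below, every library of the first group lay beyond all libraries of the second. The exceptions, with 2 of 3 libraries beyond, were Acta2 and Tnnt2 after 10 days of TAC, Hmox1 and Pdgfra after 4 days and Col3a1 and Myh6 after 10 days of swimming. Comparisons of TAC or swim fibroblasts with sedentary or sham fibroblasts therefore coincide with this division of the libraries. Comparisons within a side do not cross it but are not free of the trend. The rank correlation of fold change and length was 0.534 for 10 day against 4 day swim and 0.232 for 10 day swim against 10 day TAC (-0.432 with GC content), beside -0.536 for 10 day TAC against sedentary.

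**Figure D1:**
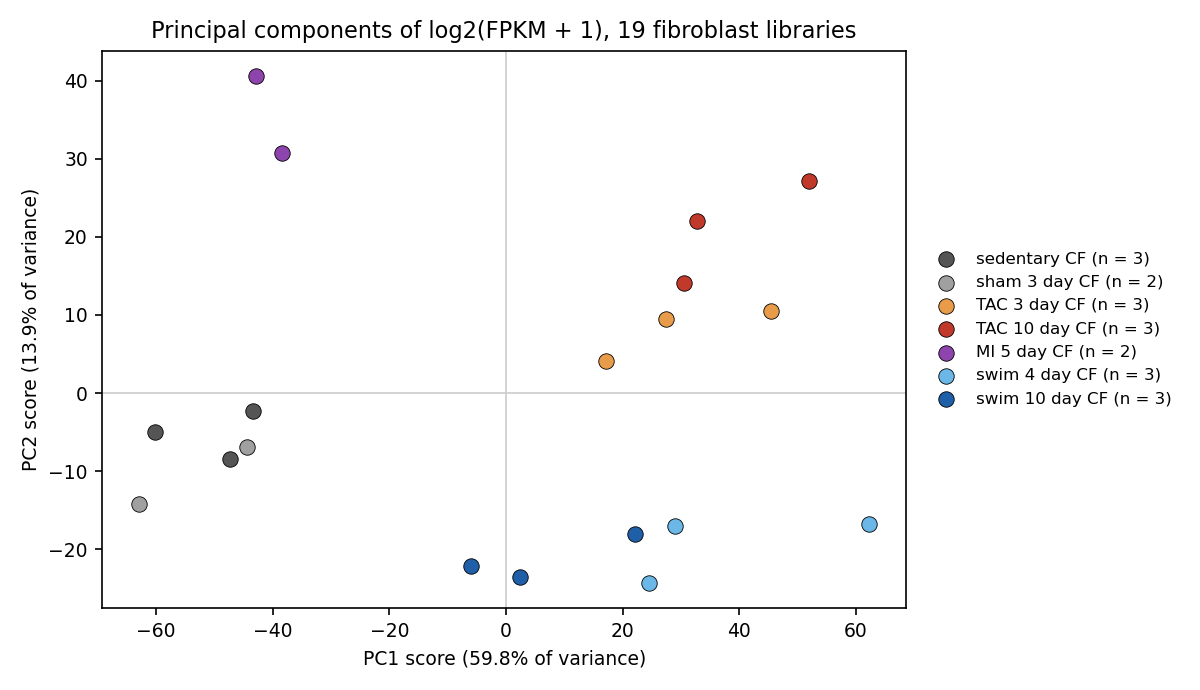
Scores of the 19 fibroblast libraries on the first (horizontal, 59.8% of variance) and second (vertical, 13.9%) principal components of log2(FPKM + 1), without units; each point is a library, coloured by group. The MI libraries (PC1 -42.9 and -38.4) sit on the side of the sedentary and sham libraries.

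**Figure D2:**
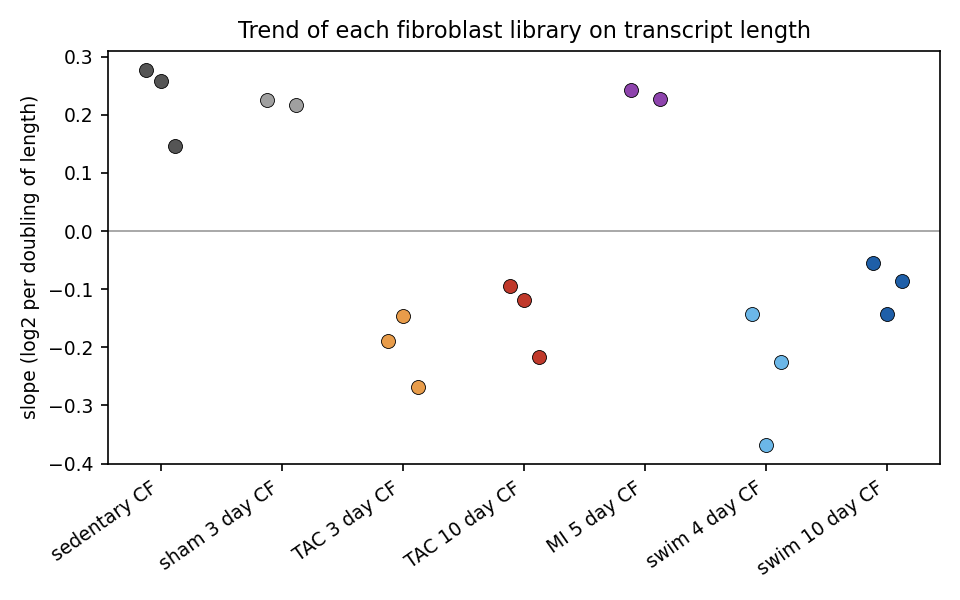
Slope of expression on transcript length (vertical axis, log2 per doubling of length) in each fibroblast library; each point is a library, in columns by group. The lowest slope among sedentary, sham and MI libraries was 0.147 and the highest among TAC and swim libraries was -0.0544.

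TAC was compared with sham at 3 days to ask what fibroblasts express early in pressure overload. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20848543 to 20920918, mm10, a listed locus that spans a second gene), rose by 3.62 log2 units (SE 0.502, adjusted p = 2.43e-05), from 18.6 ± 6.63 FPKM (SD, n = 2) to 264 ± 138 (n = 3). S100a4, a calcium-binding protein of activated fibroblasts, rose by 3.45 (SE 0.333, adjusted p = 1.62e-06). Tagln, an actin-binding protein of smooth muscle and myofibroblasts, rose by 3.18 (SE 0.423, adjusted p = 1.43e-05), from 2.47 ± 0.699 to 30.7 ± 6.37 FPKM. Col1a1, a chain of type I collagen (chromosome 11, 94936270 to 94951856), rose by 2.07 (SE 0.369, adjusted p = 0.000178), from 28.0 ± 15.3 to 114 ± 23.7 FPKM. Eln, which encodes elastin, rose by 1.94 (SE 0.361, adjusted p = 0.000256). Plac8 (3.60), Ube2c (1.92), which acts in mitosis, and Mfap5 (1.36) also rose. Postn, which encodes the matricellular protein periostin, had a value of -0.34 (adjusted p = 0.484), Col3a1 0.63 (adjusted p = 0.187) and Acta2, the smooth muscle actin of myofibroblasts, 0.72 (adjusted p = 0.171).

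Interferon-stimulated genes were lower after 3 days of TAC than after sham. The chemokine Ccl5 (chromosome 11, 83525779 to 83530518) had a log2 fold change of -5.51 (SE 0.588, adjusted p = 4.36e-06), from 120 ± 63.3 to 1.52 ± 0.641 FPKM, the antiviral Ifit1 (chromosome 19, 34640889 to 34650009) one of -4.86 (SE 1.05, adjusted p = 0.00139) and Ifnb1, interferon beta, one of -3.73 (SE 0.623, adjusted p = 0.000154). Of 26 interferon-stimulated genes, 16 fell and 1 rose (18 and 1 adjusted over the list alone; Fisher's exact test for the falls, adjusted p = 0.00188; camera, adjusted p = 0.000817; adjusted p = 0.923 with an estimated correlation). The list lost this without sham replicate 1 (7 fell, adjusted p = 0.744) and without TAC replicate 1 (12 fell, adjusted p = 0.0546). Of 26 chemokines and cytokines, 8 fell and 1 rose (adjusted p = 0.883), with Tnf at -2.79, Il1a at -2.69 and Cxcl2 at -2.52, and of 18 complement and coagulation genes 7 fell and 3 rose (adjusted p = 0.611), C3 having a log2 fold change of -2.99 (SE 0.469, adjusted p = 6.32e-05). The same direction was seen for Ptprc, the leukocyte antigen CD45, at -2.40 (SE 0.277, adjusted p = 4.55e-06), whereas 6 macrophage and monocyte markers rose and 7 fell of 24 tested (Fisher's exact test, adjusted p = 0.785 and 0.969). The mean level of 18 T, B and NK lymphocyte markers was 0.588 to 0.754 log2 units in the 12 TAC and swim libraries and 0.946 to 1.1 in the sedentary and sham ones. Without Ccl5, a member, these ranges overlapped (0.524 to 0.701 and 0.577 to 0.824). Only 3 members were expressed enough to be tested (2 fell, adjusted p = 0.329). Pdgfra, a receptor of resting fibroblasts, had a log2 fold change of -1.44 (SE 0.297, adjusted p = 0.000624). Of 26 immediate early genes 7 fell (6 adjusted over the list alone) and 0 rose (falls, adjusted p = 1; shortage of rises, adjusted p = 0.000831), among them Atf3 at -1.44 (SE 0.241, adjusted p = 9.84e-05) and Klf6 at -1.48.

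Genes of energy supply and translation were higher after 3 days of TAC, beside the shift toward short transcripts. Of 32 nuclear genes of oxidative phosphorylation 29 rose (Fisher's exact test, adjusted p = 1.49e-09). Of 22 ribosomal protein genes 21 rose (adjusted p = 5.01e-08). Of 20 other antioxidant enzymes 15 rose and 3 fell (adjusted p = 0.00204), and all 8 mitosis genes rose (adjusted p = 0.00488). For each of these lists the camera test gave adjusted p = 0.923 with an estimated correlation. Ndufa2, of respiratory complex I, rose by 2.66 (SE 0.323, adjusted p = 6.51e-06), Rps14 by 2.84 and Gpx1, a glutathione peroxidase, by 2.47. After removal of the trend on length and GC content 28 oxidative phosphorylation, 18 ribosomal, 13 antioxidant and 5 mitosis genes were called higher, the last with adjusted p = 0.0688, and Rps14 had a log2 fold change of 1.70. Rn45s rose by 3.84 (SE 0.908, adjusted p = 0.00249) and Lars2, the mitochondrial leucyl-tRNA synthetase, by 3.80 (SE 0.555, adjusted p = 4.06e-05). The cardiac myosin gene Myh6 had a log2 fold change of -2.002 (adjusted p = 0.0109), a call lost without sham replicate 1 (-2.04, adjusted p = 0.053) and without sham replicate 2 (-1.96, adjusted p = 0.0565). The genes Mt1 (0.19), Mt2 (0.37), Nqo1 (0.35), Hmox1 (-1.18), Tcf21 (-0.20), Tnnt2 (-0.36) and Pecam1 (-0.24) did not pass the test. Ndufs5, listed near 0 in the sham libraries, is given no fold. In all, 2953 genes rose and 2430 fell of 9425 tested (5383 called; 4558 in the authors' deposited table, 2210 higher and 2348 lower), 2991 of which were also called the same way after removal of the length and GC trend. With every library scaled to the same median the split was 2434 higher and 3134 lower.

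Fibroblasts 10 days after TAC were compared with sedentary fibroblasts to ask what marks established pressure overload. Matrix genes were among the largest rises. Cthrc1, a secreted protein of activated fibroblasts (chromosome 15, 39076932 to 39087119), rose by 4.31 log2 units (SE 0.596, adjusted p = 2.34e-05), from 0.154 ± 0.0721 FPKM (SD, n = 3) to 34.9 ± 38.0 (n = 3). Eln (chromosome 5, 134702596 to 134747254) rose by 3.95 (SE 0.323, adjusted p = 4.6e-07), from 5.36 ± 1.88 to 94.6 ± 13.8 FPKM. Thbs4, which encodes thrombospondin 4, rose by 3.74 (SE 0.246, adjusted p = 9.36e-08). Col1a1 rose by 2.83 (SE 0.33, adjusted p = 3.07e-06), to 182 ± 63.8 FPKM from 24.6 ± 7.21. Postn (chromosome 3, 54361107 to 54391041) rose by 2.69 (SE 0.358, adjusted p = 9.79e-06), to 54.7 ± 12.8 FPKM from 7.91 ± 3.00. Col3a1 rose by 1.75 (SE 0.358, adjusted p = 0.000455). Of 18 collagens 12 rose and 0 fell (Fisher's exact test, adjusted p = 0.111; camera, adjusted p = 0.0188; adjusted p = 0.917 with an estimated correlation), and 16 rose after removal of the length and GC trend (Fisher's exact test, adjusted p = 3.28e-05). Acta2 rose by 1.10 (SE 0.391, adjusted p = 0.0208), a call lost without sedentary replicate 2 (0.69, adjusted p = 0.122), TAC replicate 1 (1.0, adjusted p = 0.0604) or TAC replicate 3 (0.93, adjusted p = 0.0837) and after the correction for length and GC content (0.83, adjusted p = 0.0613). Timp1 rose by 1.82 (SE 0.449, adjusted p = 0.00217), a call lost after that correction (0.81, adjusted p = 0.104).

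Chemokine, interferon-stimulated and NRF2 genes were lower after 10 days of TAC. Of 26 chemokines and cytokines 19 fell and 1 rose (Fisher's exact test, adjusted p = 2.25e-05; camera, adjusted p = 3.38e-05). Of 26 interferon-stimulated genes 19 fell and 1 rose (Fisher's exact test, adjusted p = 1.08e-05; camera, adjusted p = 5.06e-05); both gave adjusted p = 0.917 with an estimated correlation. Between 13 and 23 interferon-stimulated genes fell when a sedentary library was left out, at adjusted p of 0.00905 or less. Cxcl5, a neutrophil attractant, had a log2 fold change of -4.80 (SE 0.811, adjusted p = 0.000154), Ifit1 one of -4.98 (SE 0.937, adjusted p = 0.000393), Ccl5 one of -4.72 (SE 0.526, adjusted p = 3.56e-06) and Il6 one of -3.53 (SE 0.835, adjusted p = 0.00202). The metal-binding metallothioneins Mt2 (chromosome 8, 94172618 to 94173567) and Mt1 (94179089 to 94180327) had log2 fold changes of -2.50 (SE 0.419, adjusted p = 8.67e-05; 270 ± 86.6 to 45.7 ± 8.87 FPKM) and -1.16 (SE 0.24, adjusted p = 0.000474; 150 ± 23.8 to 66.5 ± 13.4 FPKM). All 3 metallothioneins tested fell (Fisher's exact test, adjusted p = 0.106; camera, adjusted p = 0.0637). Of 28 genes of the NRF2 antioxidant response 15 fell and 6 rose (Fisher's exact test, adjusted p = 0.0353; camera, adjusted p = 0.0476; adjusted p = 0.917 with an estimated correlation), which was lost without TAC replicate 2 (14 fell, adjusted p = 0.0507). The study singled out these 2 lists on the same samples, so they are not independent evidence. Hmox1, heme oxygenase 1 (chromosome 8, 75093618 to 75100593), had a log2 fold change of -2.56 (SE 0.635, adjusted p = 0.00261), Txnrd1 one of -2.54 and Gclm one of -2.15, while Nqo1 was at 0.22 (adjusted p = 0.404). Ptprc was lower (-1.93, SE 0.247, adjusted p = 6.82e-06), beside 9 macrophage and monocyte markers that rose and 3 that fell (Fisher's exact test, adjusted p = 0.949 and 0.378). Pdgfra was lower as well (-1.16, SE 0.266, adjusted p = 0.00113), with 11 of 22 resting fibroblast markers lower and 6 higher (Fisher's exact test for the falls, adjusted p = 0.112).

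Respiratory and ribosomal genes rose after 10 days of TAC with the shift toward short transcripts. Of 32 oxidative phosphorylation genes 29 rose (Fisher's exact test, adjusted p = 5.97e-07). Of 22 ribosomal protein genes 21 rose (adjusted p = 4.41e-06) and all 8 mitosis genes rose (adjusted p = 0.0381), each with adjusted p = 0.917 with an estimated correlation. After the correction for length and GC content 31, 16 and 5 were called higher, with adjusted p = 3.17e-13, 0.000804 and 0.235. Rn45s rose by 3.41 (SE 0.812, adjusted p = 0.00213). Cardiomyocyte transcripts moved with this group: 11 of 19 cardiomyocyte markers rose and 0 fell (10 and 0 adjusted over the list alone; Fisher's exact test, adjusted p = 0.266), Nppa, atrial natriuretic peptide, rose by 3.34 (SE 0.652, adjusted p = 0.00045), and 4 markers were called higher and 1 lower after the correction. Of 20 endothelial markers 10 rose and 3 fell (Fisher's exact test, adjusted p = 0.724), 8 and 1 after the correction. Of 12 pericyte and smooth muscle markers 7 rose and 3 fell (adjusted p = 0.461), 3 and 1 after the correction. The mean level of the endothelial list was 3.57 to 4.42 log2 units in the TAC libraries and 2.89 to 3.37 in the sedentary ones. Tnnt2, cardiac troponin T, was 1.21 higher (adjusted p = 0.0492), a call lost without sedentary replicate 1 (1.30, adjusted p = 0.0741), sedentary replicate 2 (0.66, adjusted p = 0.237), TAC replicate 1 (1.02, adjusted p = 0.141) or TAC replicate 3 (0.92, adjusted p = 0.176). Myh6 (-0.12), Pecam1 (-0.04) and Tcf21 (-0.48) did not pass the test. Altogether 3654 genes rose and 2541 fell (6195 called, 5475 in the authors' deposited table), and 3754 were called the same way after the correction. The median gene was 0.124 higher in TAC, and scaling to the same median gave 2784 higher and 3540 lower.

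MI fibroblasts were compared with sedentary fibroblasts to ask what marks the response to an infarct at 5 days. Extracellular matrix genes were among the largest rises. Cthrc1 rose by 6.74 log2 units (SE 0.666, adjusted p = 5.39e-06), from 0.154 ± 0.0721 FPKM (SD, n = 3) to 123 ± 11.5 (n = 2). Postn rose by 5.54 (SE 0.4, adjusted p = 5.05e-08), from 7.91 ± 3.00 to 395 ± 36.1 FPKM. Col1a1 rose by 4.59 (SE 0.369, adjusted p = 1.74e-07), from 24.6 ± 7.21 to 599 ± 84.5 FPKM. Col3a1 (chromosome 1, 45311538 to 45349706) rose by 4.23 (SE 0.4, adjusted p = 1.32e-06), from 25.3 ± 10.8 to 459 ± 49.2 FPKM. Spp1, osteopontin, rose by 4.98 (SE 0.441, adjusted p = 9.7e-07), Fn1, fibronectin, by 4.12 (SE 0.317, adjusted p = 9.27e-08). Lox, which crosslinks collagen and elastin, rose by 4.06 (SE 0.303, adjusted p = 6.95e-08), Thbs4 by 4.39, Eln by 3.26 and Timp1 by 3.34 (SE 0.502, adjusted p = 0.000278). Of 18 collagens 13 rose and 0 fell (14 adjusted over the list alone; Fisher's exact test, adjusted p = 1.91e-08; adjusted p = 0.13 with an estimated correlation). Of 17 matricellular proteins 12 rose and 0 fell (14 adjusted over the list alone; adjusted p = 7.12e-08), a result that held at adjusted p = 0.0185 with an estimated correlation. Of 20 enzymes that crosslink or mature collagen 13 rose and 1 fell (adjusted p = 7.12e-08; adjusted p = 0.13 with an estimated correlation). Of 28 other matrix proteins 14 rose and 2 fell (adjusted p = 1.48e-06; adjusted p = 0.431 with an estimated correlation).

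Contractile, mitotic and developmental genes rose in the same MI libraries. Of 22 myofibroblast genes 11 rose and 0 fell (16 adjusted over the list alone; Fisher's exact test, adjusted p = 2.61e-05; adjusted p = 0.282 with an estimated correlation), Tagln rising by 3.95 (SE 0.423, adjusted p = 5.38e-06). Acta2 rose by 2.16 (SE 0.437, adjusted p = 0.00345; 54.7 ± 41.2 against 10.6 ± 5.75 FPKM), a call lost without MI replicate 2 (1.32, adjusted p = 0.174). All 8 mitosis genes rose (adjusted p = 1.26e-05; adjusted p = 0.431 with an estimated correlation), as did 9 of 17 epicardial and embryonic cardiac transcription factors (adjusted p = 2.64e-05; adjusted p = 0.207 with an estimated correlation), among them Snai1 (1.68) and Meox1 (1.22). Of 29 growth factors and receptors 12 rose and 3 fell (adjusted p = 4.81e-05; adjusted p = 0.431 with an estimated correlation), including Tgfb3 (1.81), Ptn (2.87) and Mdk (2.69). Of 18 Wnt, BMP and Notch genes 8 rose and 1 fell (adjusted p = 0.00109; adjusted p = 0.431 with an estimated correlation), including Sfrp2 (3.27) and Jag1 (1.71). Without MI replicate 2 the myofibroblast list (3 rose, adjusted p = 0.141) and the mitosis list (0 rose, adjusted p = 1) were lost, while the transcription factor, growth factor and Wnt lists passed (adjusted p = 2.31e-05, 0.000794 and 5.45e-06).

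Chemokine and NRF2 genes were lower after MI, and resting fibroblast genes only with both MI libraries or without replicate 1. Of 22 resting fibroblast markers 10 fell and 2 rose (12 and 3 adjusted over the list alone; Fisher's exact test, adjusted p = 4.25e-09; adjusted p = 0.431 with an estimated correlation), Hsd11b1 having a log2 fold change of -2.26 (SE 0.326, adjusted p = 0.000138). Without MI replicate 2, 0 of them fell (adjusted p = 1), beside 4 chemokines (adjusted p = 7.93e-06) and 3 NRF2 genes (adjusted p = 0.000486). Without replicate 1 the numbers were 14, 4 and 4. Of 26 chemokines and cytokines 7 fell and 2 rose (adjusted p = 2.64e-05; adjusted p = 0.431 with an estimated correlation), with Tnf at -3.39 (SE 0.507, adjusted p = 0.000267), Ccl3 at -2.88 and Ccl4 at -2.52. Of 28 NRF2 genes 6 fell and 0 rose (adjusted p = 0.000371; adjusted p = 0.431 with an estimated correlation), including the glutathione transferases Gstm1 at -2.11 (SE 0.272, adjusted p = 4.06e-05) and Gsta3 at -1.82; that list was emphasised by the study and is not independent evidence. Mt1 (-0.74, adjusted p = 0.0864), Mt2 (-0.78, adjusted p = 0.338) and Tcf21 (-1.12, adjusted p = 0.0918) did not pass, nor did Nqo1, Hmox1, Pdgfra, Myh6, Tnnt2, Ptprc and Pecam1, with values between -0.91 and -0.03. No oxidative phosphorylation or ribosomal gene was called, and 3 of 24 macrophage and monocyte markers rose (5 adjusted over the list alone; Fisher's exact test, adjusted p = 1). With 2 MI libraries, 842 genes rose and 221 fell (1063 called, 2291 at an unadjusted p under 0.05, 1766 in the authors' deposited table). The count was 253 without MI replicate 2 (231 higher, 22 lower), 707 without MI replicate 1 (518 and 189) and 1300 without the sedentary wt replicate (1035 and 265); the median gene was 0.105 higher in MI, and scaling to the same median gave 572 higher and 403 lower. Among fibroblast libraries the labels carry a date only for both MI libraries and for the sedentary wt replicate, and these 2 dates differ, so a batch effect cannot be told apart from the group.

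**Figure D3:**
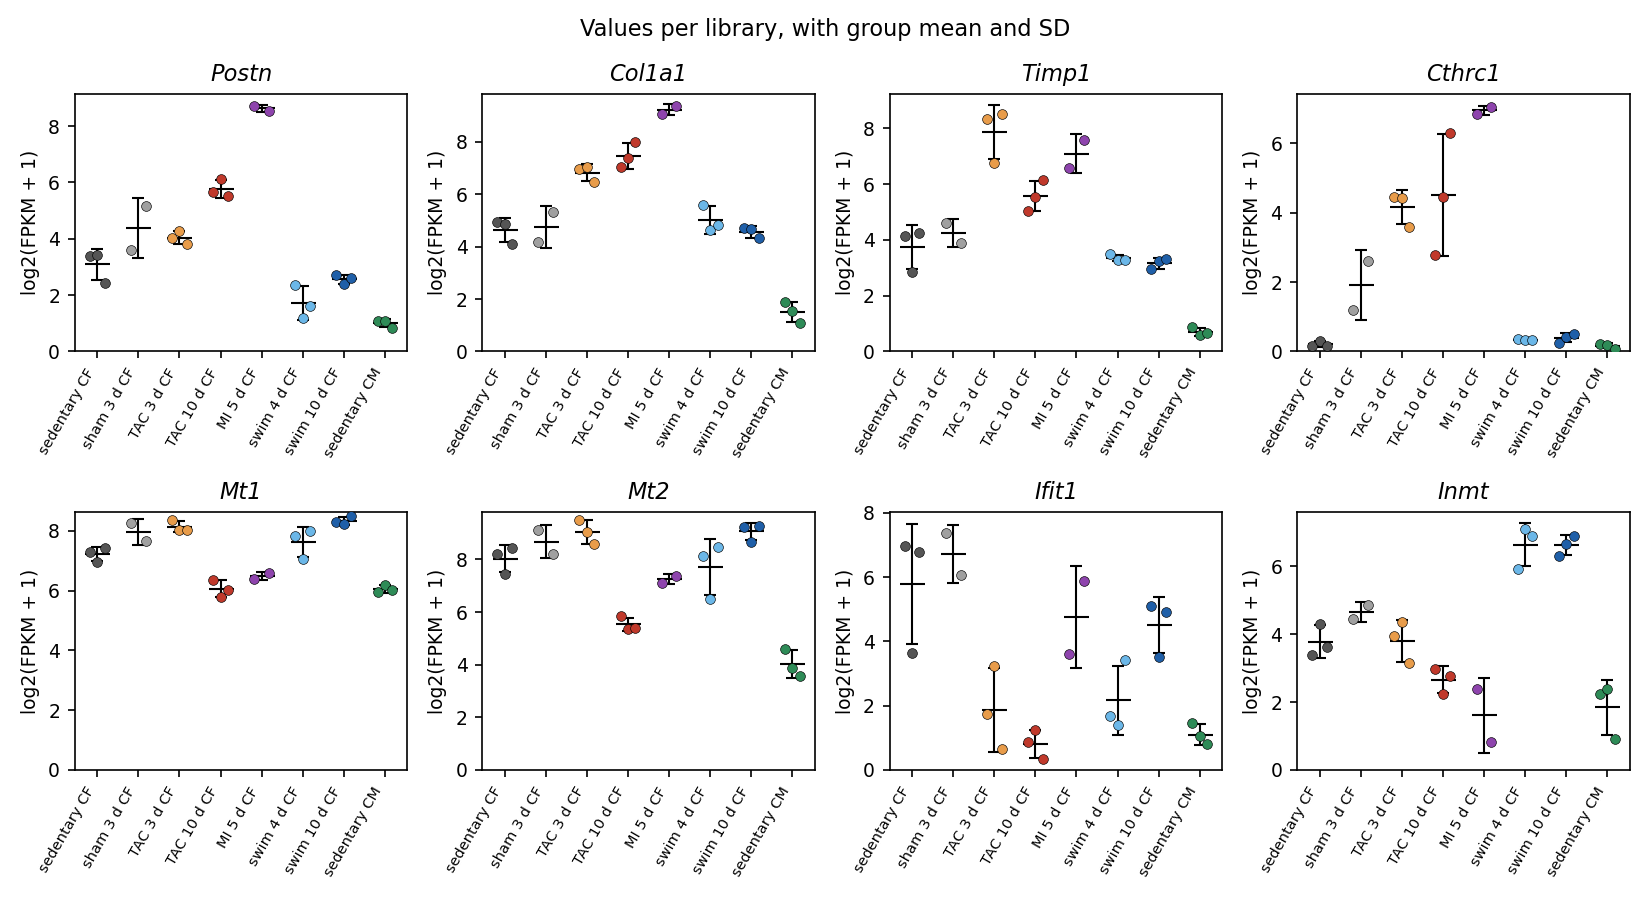
Expression of 8 genes in each library (points; vertical axis log2(FPKM + 1)), with the mean and SD of each of the 8 groups. Postn averaged 395 FPKM after MI and 54.7 after 10 days of TAC, against 7.91 in sedentary and 4.94 in 10 day swim fibroblasts.

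Fibroblasts of mice that swam for 4 days were compared with sedentary fibroblasts to ask how the start of exercise is reflected. Hist1h1c, a linker histone (chromosome 13, 23738807 to 23740367), rose by 3.60 log2 units (SE 0.357, adjusted p = 1.05e-06), from 3.96 ± 0.931 FPKM (SD, n = 3) to 60.7 ± 19.6 (n = 3). The interferon-inducible Ifi27l2a rose by 3.03 (SE 0.279), from 63.2 ± 6.27 to 525 ± 64.0 FPKM and Gpx1 by 3.03 (SE 0.308, adjusted p = 1.08e-06). The complement component C1qa, made by macrophages (chromosome 4, 136895916 to 136898844), rose by 2.86 (SE 0.278, adjusted p = 9.51e-07), from 60.4 ± 11.4 to 443 ± 79.4 FPKM. The insulin-like growth factor binding proteins Igfbp6 (2.18) and Igfbp4 (2.08), the inhibitor of differentiation Id3 (2.02) and the early response genes Jund (1.81), Ier2 (1.64) and Btg2 (1.32) also rose. Of 26 immediate early genes 9 rose and 3 fell (7 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.825). Once the length and GC trend was removed, C1qa stood at 1.64 (adjusted p = 7.32e-05), Ier2 at 0.68 (adjusted p = 0.00932) and Jund at 0.91 (adjusted p = 0.0734).

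Endothelial and interferon-stimulated genes were lower after 4 days of swimming. Ccl5 had a log2 fold change of -5.11 (SE 0.526, adjusted p = 1.72e-06), the endothelial adhesion molecules Selp and Sele ones of -4.60 (SE 0.608, adjusted p = 1.49e-05) and -3.97 (SE 0.716, adjusted p = 0.000228), and Thbs1 one of -4.36 (SE 0.762, adjusted p = 0.000176; 19.4 FPKM against 352). Of 26 interferon-stimulated genes 17 fell and 1 rose (Fisher's exact test, adjusted p = 0.00117; camera, adjusted p = 0.000138; 19 lower after the length and GC correction). Between 12 and 23 fell when a sedentary library was left out, and without the wt replicate the test was lost (adjusted p = 0.0821). Of 26 chemokines and cytokines 10 fell and 5 rose (Fisher's exact test, adjusted p = 0.39). Of 20 endothelial markers 11 fell and 2 rose (11 and 3 adjusted over the list alone; adjusted p = 0.0241, and 0.0914 without sedentary replicate 2), among them Cdh5, endothelial cadherin (chromosome 8, 104101625 to 104144502), at -2.49 (SE 0.295, adjusted p = 2.99e-06) and Pecam1 at -1.82 (SE 0.364, adjusted p = 0.000367; 3.36 ± 0.566 against 14.5 ± 2.65 FPKM). Of 18 collagens 8 fell and 0 rose (Fisher's exact test, adjusted p = 0.15; camera, adjusted p = 0.0238), but 3 fell and 2 rose after the correction. Of 22 myofibroblast genes 10 fell and 1 rose (Fisher's exact test, adjusted p = 0.241; camera, adjusted p = 0.0133). All of these lists had adjusted p = 0.999 with an estimated correlation. Postn was lower, at -1.36 (SE 0.358, adjusted p = 0.00322; 2.52 ± 1.504 against 7.91 ± 3.00 FPKM), Fn1 at -1.65 (SE 0.283, adjusted p = 8.75e-05), Ptprc at -1.52 (SE 0.247, adjusted p = 5.37e-05) and Myh6 at -1.99 (SE 0.54, adjusted p = 0.00477).

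Energy, translation and antioxidant genes again rose with the shift toward short transcripts: 30 of 32 oxidative phosphorylation genes (Fisher's exact test, adjusted p = 3.98e-08), 21 of 22 ribosomal genes (adjusted p = 4.33e-06) and 17 of 20 other antioxidant enzymes, with 1 lower (adjusted p = 0.00117). Each had adjusted p = 0.999 with an estimated correlation, and 27, 19 and 12 were called higher after the correction for length and GC content. Transcripts of red blood cells moved with this group: all 5 erythroid genes tested were called higher (Fisher's exact test, adjusted p = 0.0695), but 0 after the correction, and the beta globin Beta-s, 4.52 higher (adjusted p = 0.017), lost its call without sedentary replicate 1 (2.54, adjusted p = 0.0804). Of 24 macrophage and monocyte markers 9 rose and 2 fell (Fisher's exact test, adjusted p = 0.913). Hmox1 (-1.91, adjusted p = 0.0157) lost its call without the sedentary wt replicate (-1.42, adjusted p = 0.0734) and without swim replicate 2 (-1.20, adjusted p = 0.0997). Pdgfra (-0.65, adjusted p = 0.0411) lost its call without sedentary replicate 1 (-0.60, adjusted p = 0.105) or 2 (-0.58, adjusted p = 0.102), without swim replicate 2 (-0.45, adjusted p = 0.188) or 3 (-0.59, adjusted p = 0.0976), and after the correction (-0.03, adjusted p = 0.908). Mt1 (0.41), Mt2 (-0.33), Nqo1 (-0.06), Col1a1 (0.38), Col3a1 (-0.52), Acta2 (-0.46), Timp1 (-0.39), Tcf21 (0.85) and Tnnt2 (0.18) did not pass the test. In total 3602 genes rose and 2477 fell (6079 called, 4896 in the authors' deposited table), 3452 of them called the same way after the correction. The median gene was 0.127 higher, and scaling to the same median gave 2694 higher and 3588 lower.

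After 10 days of swimming, fibroblasts were compared with sedentary ones to ask what sustained exercise changes. Inmt, an indolethylamine methyltransferase (chromosome 6, 55170627 to 55174990), rose by 2.84 log2 units (SE 0.408, adjusted p = 7.65e-05), from 13.3 ± 4.96 FPKM (SD, n = 3) to 99.0 ± 19.95 (n = 3). Dbp, a clock-controlled transcription factor, rose by 2.60 (SE 0.557, adjusted p = 0.00183) and C1qa by 1.94 (SE 0.278, adjusted p = 6.93e-05). Mt1 rose by 1.11 (SE 0.24, adjusted p = 0.00156), from 150 ± 23.8 to 322 ± 32.9 FPKM, a call lost after the correction for length and GC content (0.34, adjusted p = 0.357), and Mt2 was at 1.03 (adjusted p = 0.0556; 542 ± 116 against 270 ± 86.6 FPKM). The antioxidant enzymes Sod1 (1.62), Prdx5 (1.62) and Prdx2 (1.60) rose with 17 of 20 members of their list (Fisher's exact test, adjusted p = 6.16e-05). So did 28 of 32 oxidative phosphorylation genes (30 adjusted over the list alone; adjusted p = 1.88e-08) and 21 of 22 ribosomal genes (adjusted p = 4.38e-08). These lists had adjusted p = 0.962 with an estimated correlation, and 12, 16 and 19 of their members were called higher after the correction. Rn45s rose by 2.46 (adjusted p = 0.0247), a call lost without sedentary replicate 1 (2.31, adjusted p = 0.0782) or 2 (2.42, adjusted p = 0.0541) and without swim replicate 1 (2.51, adjusted p = 0.0508) or 2 (2.14, adjusted p = 0.0954).

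Interferon-stimulated genes and collagens were lower after 10 days of swimming. Of 26 interferon-stimulated genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0158; camera, adjusted p = 1.12e-05; 13 lower after the correction), including Gvin1 at -2.46 (SE 0.386, adjusted p = 0.000167), Mx1 at -1.97 (SE 0.354, adjusted p = 0.00051) and Gbp2 at -1.70. The mean level of this list was 3.93, 2.33 and 4.37 log2 units in sedentary replicates 1, 2 and wt, so replicate 2 lay among the swim libraries. Without replicate 2 the falls numbered 18 (Fisher's exact test, adjusted p = 5.76e-07). The test was lost without sedentary replicate 1 (7 fell, adjusted p = 0.115) or wt (7, adjusted p = 0.202) and without swim replicate 2 (7, adjusted p = 0.136) or 3 (8, adjusted p = 0.138). Ccl5 had a log2 fold change of -3.98 (SE 0.526, adjusted p = 5.8e-05), Cxcl5 one of -3.14 (SE 0.811, adjusted p = 0.00666), Selp one of -2.68 (SE 0.608, adjusted p = 0.00276) and Cdh5 one of -1.60 (SE 0.295, adjusted p = 0.000466). Of 18 collagens 7 fell and 0 rose (Fisher's exact test, adjusted p = 0.0228; camera, adjusted p = 0.00156; 4 lower after the correction, adjusted p = 0.342; lost without sedentary replicate 1, adjusted p = 0.453, or 2, 0.703, and without swim replicate 2, 0.205, or 3, 0.139), with the basement membrane chain Col4a1 at -1.35 (SE 0.219, adjusted p = 0.000169), and Mmp14, a membrane collagenase, was at -1.26. These lists had adjusted p = 0.962 with an estimated correlation. Of 20 endothelial markers 7 fell and 1 rose (adjusted p = 0.0586). Of 24 macrophage and monocyte markers 7 rose and 2 fell (adjusted p = 1), with Ptprc at -1.04 (SE 0.247, adjusted p = 0.00289).

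Of the genes tied to fibrosis, 4 did not pass the test after 10 days of swimming. Col1a1 was at -0.07 (adjusted p = 0.879; 22.8 ± 3.40 against 24.6 ± 7.21 FPKM), Postn at -0.52 (adjusted p = 0.249), Acta2 at -0.52 (adjusted p = 0.299) and Timp1 at -0.58 (adjusted p = 0.314). Col3a1 had a log2 fold change of -0.98 (adjusted p = 0.0349), a call lost without sedentary replicate 1 (-0.84, adjusted p = 0.126) or 2 (-0.72, adjusted p = 0.14) and without swim replicate 2 (-0.99, adjusted p = 0.0781) or 3 (-0.86, adjusted p = 0.11). Myh6 had one of -1.46 (adjusted p = 0.0397), lost without sedentary replicate 1 (-1.20, adjusted p = 0.146) or wt (-1.09, adjusted p = 0.137) and without swim replicate 2 (-1.17, adjusted p = 0.156) or 3 (-1.22, adjusted p = 0.131). Nqo1 (-0.02), Hmox1 (-0.50), Tcf21 (0.69), Pdgfra (-0.26), Tnnt2 (0.19) and Pecam1 (-0.83) did not pass the test. The comparison called 2823 genes higher and 1284 lower (4107 called, 3684 in the authors' deposited table), 1809 of them also after the correction for length and GC content, which called 2710 genes. The median gene was 0.136 higher, and scaling to the same median turned the split to 1602 higher and 2620 lower.

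**Figure D4:**
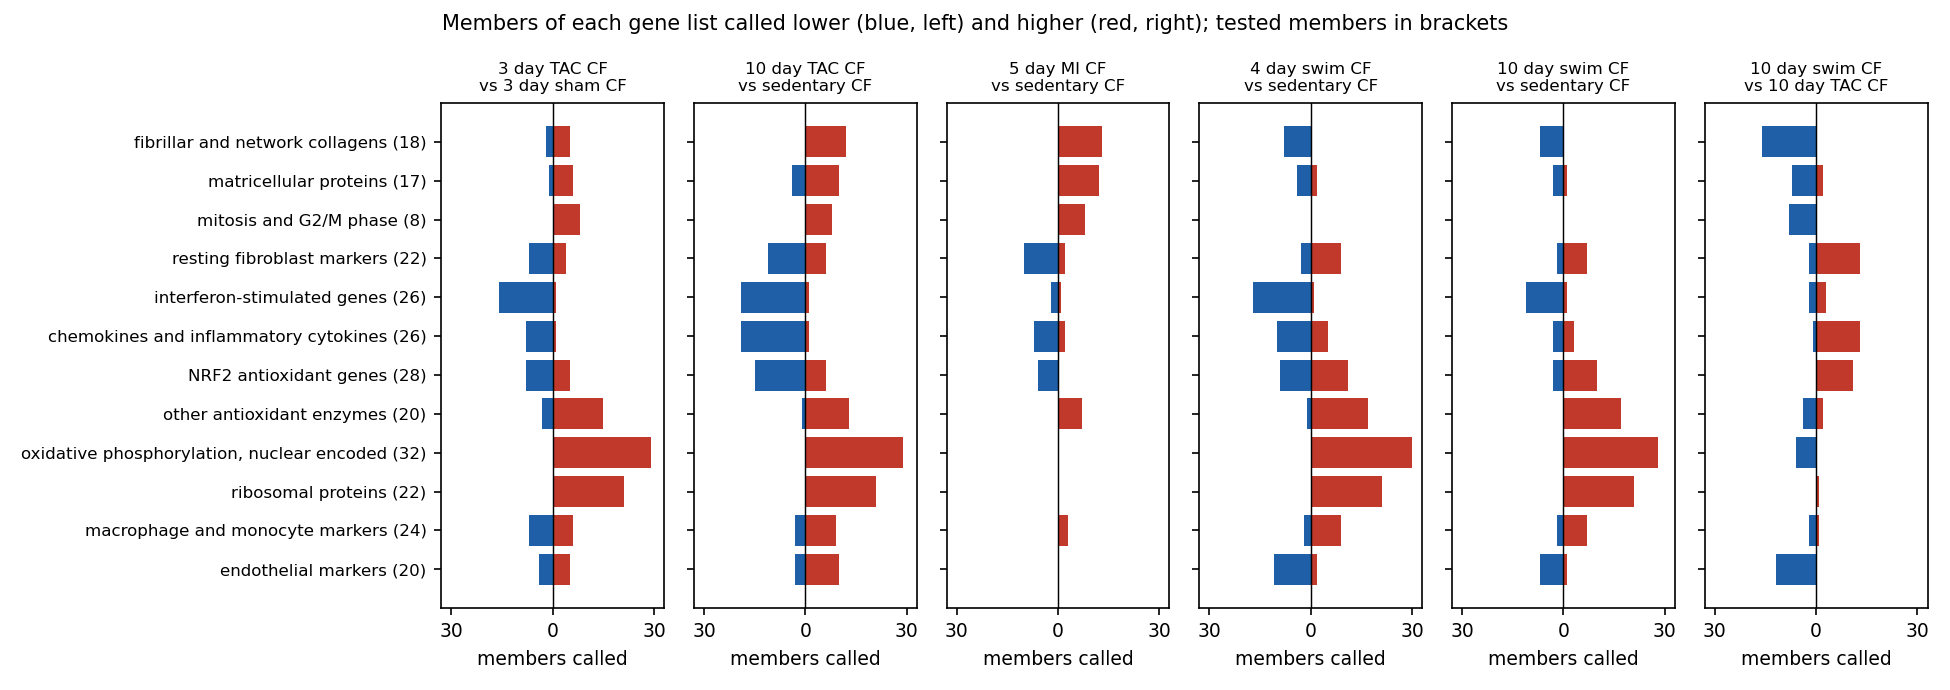
Number of members of 12 gene lists called lower (bars to the left) and higher (bars to the right) in 6 comparisons; the horizontal axis counts members and the tested number stands in brackets. Collagens were called higher in 13 of 18 cases after MI and lower in 16 of 18 in 10 day swim against 10 day TAC.

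Sham was compared with sedentary to ask what the operation itself changes. Ccl8, a chemokine that attracts monocytes (chromosome 11, 82115185 to 82116799), rose by 2.499 log2 units (SE 0.373, adjusted p = 0.033), from 6.68 ± 2.83 FPKM (SD, n = 3) to 43.8 ± 23.6 (n = 2). That call was lost without sedentary replicate 2 (2.28, adjusted p = 0.0703), the sedentary wt replicate (2.44, adjusted p = 0.119) or sham replicate 2 (1.93, adjusted p = 0.998) and after the correction for length and GC content (adjusted p = 0.101). The other gene called by limma was the predicted gene Gm12505 (0.93, adjusted p = 0.0429), named after its values were seen. No list passed Fisher's exact test. Adjusted over the list alone, 6 of 24 macrophage and monocyte markers were higher (median 0.73; camera, adjusted p = 8.4e-10; adjusted p = 0.48 with an estimated correlation), 6 of 18 complement and coagulation genes were higher (adjusted p = 5.39e-05; adjusted p = 0.611 with an estimated correlation), and 7 of 20 endothelial markers were lower (median -0.50; adjusted p = 4.56e-19; adjusted p = 0.441 with an estimated correlation). Postn was at 1.29 (adjusted p = 0.418), Pecam1 at -0.90 (adjusted p = 0.703), Mt1 at 0.72 (adjusted p = 0.549), Mt2 at 0.64, Ptprc at 0.68 and Timp1 at 0.50. The remaining genes named in every comparison (Nqo1, Hmox1, Col1a1, Col3a1, Acta2, Tcf21, Pdgfra, Myh6 and Tnnt2) had values from -0.38 to 0.72, with no call. In all 2 genes rose and 0 fell, against 647 at an unadjusted p under 0.05 and 252 in the authors' deposited table (181 higher, 71 lower). Recovery in simulation, with 200 changed genes, does not carry over to so few calls. The count became 142 without sham replicate 1, 0 without sham replicate 2 and 1 without any one sedentary library.

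Fibroblasts after 10 days of swimming were compared directly with those after 10 days of TAC, the contrast of exercise with disease at a matched time. Without a sham group at 10 days, effects of the operation on the TAC mice were not separated. Matrix genes were lower after swimming. Eln had a log2 fold change of -4.68 (SE 0.323, adjusted p = 1.55e-07; 2.73 ± 0.560 FPKM, SD, n = 3, against 94.6 ± 13.8, n = 3), Cthrc1 one of -4.12 (SE 0.596, adjusted p = 0.000286), Thbs4 one of -3.53 (SE 0.246, adjusted p = 1.55e-07). Postn had one of -3.21 (SE 0.358, adjusted p = 1.46e-05; 4.94 ± 0.657 against 54.7 ± 12.8 FPKM), Col1a1 one of -2.90 (SE 0.33, adjusted p = 1.74e-05; 22.8 ± 3.40 against 182 ± 63.8 FPKM) and Col3a1 one of -2.73 (SE 0.358, adjusted p = 6.79e-05). Timp1 (-2.40, SE 0.449, adjusted p = 0.00158) and Acta2 (-1.62, SE 0.391, adjusted p = 0.00798) were lower too. Of 18 collagens 16 fell and 0 rose (Fisher's exact test, adjusted p = 3.19e-09). Of 28 other matrix proteins 14 fell and 5 rose (adjusted p = 0.000564). Of 20 crosslinking enzymes 11 fell and 2 rose (adjusted p = 0.000739). All 8 mitosis genes fell (adjusted p = 0.000173), as did 9 of 22 myofibroblast genes (adjusted p = 0.0282). So did 4 of 6 fetal and stress cardiac genes (adjusted p = 0.0345), Nppa among them at -3.84 (SE 0.652, adjusted p = 0.00105). With an estimated correlation these lists had, in this order, adjusted p = 0.413, 0.583, 0.575, 0.511, 0.583 and 0.511. The myofibroblast list was lost without TAC replicate 2 (adjusted p = 0.0847) and without swim replicate 1 (0.0545), 2 (0.176) or 3 (0.219). The fetal list was lost without TAC replicate 1 (0.103) or 3 (0.321) or swim replicate 3 (0.268). Cardiomyocyte carry-over was not excluded for either list or Acta2: cardiomyocyte markers averaged 3.6 log2 units in TAC and 2.42 in swim.

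Metallothioneins and genes of the NRF2 antioxidant response were higher after 10 days of swimming than after 10 days of TAC. Mt2 rose by 3.53 (SE 0.419, adjusted p = 3.02e-05), at 542 ± 116 against 45.7 ± 8.87 FPKM, Mt4 (chromosome 8, 94137204 to 94139031) by 2.87 (SE 0.421, adjusted p = 0.000211) and Mt1 by 2.27 (SE 0.24, adjusted p = 8.16e-06), at 322 ± 32.9 against 66.5 ± 13.4 FPKM. The glutathione transferases Gsta3 (3.10, SE 0.273, adjusted p = 1.75e-06), Gsta2 (2.31) and Gsta1 (2.23), whose close sequence similarity leaves the share of each uncertain, were higher as well. All 3 metallothioneins rose (Fisher's exact test, adjusted p = 0.0134; camera, adjusted p = 0.000165; adjusted p = 0.413 with an estimated correlation). Of 28 NRF2 genes 11 rose and 0 fell (13 and 1 adjusted over the list alone; Fisher's exact test, adjusted p = 0.00194; adjusted p = 0.511 with an estimated correlation), but 5 without swim replicate 3 (adjusted p = 0.0516). The study chose both lists on these samples, so the counts are not independent evidence. Hmox1 rose by 2.06 (SE 0.635, adjusted p = 0.0297; 242 ± 84.3 against 57.4 ± 21.7 FPKM), a call lost without TAC replicate 3 (1.71, adjusted p = 0.126), swim replicate 1 (1.89, adjusted p = 0.112) or swim replicate 3 (1.90, adjusted p = 0.106), and Nqo1 was at -0.24 (adjusted p = 0.43). Against sedentary fibroblasts Mt2 was at -2.50 in TAC (-3.77 after the length and GC correction) and, without a call, at 1.03 in swim (adjusted p = 0.0556; 0.13 and adjusted p = 0.868 after the correction). Gsta3 was at -0.93 in TAC and 2.17 in swim (1.70 after the correction).

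Resting fibroblast, chemokine and complement genes were higher after swimming than after TAC. Inmt rose by 3.96 (SE 0.408, adjusted p = 8e-06). Ccl11, eotaxin (chromosome 11, 82057832 to 82062955), rose by 3.33 (SE 0.311, adjusted p = 2.2e-06), Gsn, the actin-severing gelsolin, by 3.01 (SE 0.491, adjusted p = 0.000604; 2015 ± 154 against 309 ± 254 FPKM) and C3 by 2.04. Of 22 resting fibroblast markers 13 rose and 2 fell (Fisher's exact test, adjusted p = 7.15e-06; adjusted p = 0.583 with an estimated correlation). Of 26 chemokines and cytokines 13 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 4.68e-05; adjusted p = 0.511 with an estimated correlation). Of 18 complement and coagulation genes 9 rose and 1 fell (adjusted p = 0.000564; adjusted p = 0.575 with an estimated correlation). Tcf21, a transcription factor of fibroblasts, rose by 1.18 (adjusted p = 0.0281), Pdgfra by 0.90 (adjusted p = 0.0224) and Ptprc by 0.89 (adjusted p = 0.0168). The Tcf21 call was lost without TAC replicate 2 (1.15, adjusted p = 0.0661) or 3 (1.12, adjusted p = 0.098) and without swim replicate 1 (1.13, adjusted p = 0.0944) or 3 (1.13, adjusted p = 0.0928). Without TAC replicate 3, swim replicate 1 and swim replicate 3 in turn, Pdgfra was at 0.57 (adjusted p = 0.141), 0.90 (adjusted p = 0.0697) and 0.90 (adjusted p = 0.0698), and Ptprc at 0.71 (adjusted p = 0.0965), 0.70 (adjusted p = 0.1) and 0.85 (adjusted p = 0.0637). Markers of other cells moved too: 12 of 20 endothelial markers fell (13 adjusted over the list alone; adjusted p = 4.68e-05; adjusted p = 0.511 with an estimated correlation), with Cdh5 at -1.76 (SE 0.295), and 6 of 19 cardiomyocyte markers fell (adjusted p = 0.123; camera, adjusted p = 0.000115; adjusted p = 0.583 with an estimated correlation), with Myh6 at -1.34 (adjusted p = 0.0813), Tnnt2 at -1.02 (adjusted p = 0.149) and Pecam1 at -0.79 (adjusted p = 0.115). In total 1031 genes rose and 1248 fell (2279 called, 2946 in the authors' deposited table). The count was 1085 without TAC replicate 3, 1027 without swim replicate 1 and 1059 without swim replicate 3.

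At the early times, 4 days of swimming was compared with 3 days of TAC, again to set exercise against disease. Timp1 had a log2 fold change of -4.50 (SE 0.449, adjusted p = 8.26e-05; 9.28 ± 0.845 FPKM, SD, n = 3, against 264 ± 138, n = 3), Spp1 one of -4.23 (SE 0.395, adjusted p = 8.26e-05), Cthrc1 one of -3.82 (SE 0.596, adjusted p = 0.0012), the acute phase protein Saa3 one of -3.40 (SE 0.494, adjusted p = 0.00067). Tagln had one of -2.80 (SE 0.378, adjusted p = 0.000265), Postn one of -2.31 (SE 0.358, adjusted p = 0.000712) and Col1a1 one of -1.81 (SE 0.33, adjusted p = 0.0027). All 8 mitosis genes fell (Fisher's exact test, adjusted p = 1.65e-08; adjusted p = 0.289 with an estimated correlation), Ube2c at -1.88 (SE 0.232, adjusted p = 0.000122). Of 17 matricellular proteins 8 fell and 1 rose (adjusted p = 5.92e-06; adjusted p = 0.289 with an estimated correlation). Of 21 hypoxia and glycolysis genes 8 fell (11 adjusted over the list alone; adjusted p = 2.85e-05; adjusted p = 0.289 with an estimated correlation), Ldha at -1.07 (SE 0.214, adjusted p = 0.00498). Of 18 collagens 5 fell (10 adjusted over the list alone; adjusted p = 0.00283; adjusted p = 0.531 with an estimated correlation). Higher after swimming were Hist1h1c by 2.85 (SE 0.357, adjusted p = 0.000145), Inmt by 2.83 (SE 0.408, adjusted p = 0.000446) and Tnf by 2.72 (SE 0.454, adjusted p = 0.00157). Of 22 resting fibroblast markers 9 rose and 0 fell (12 adjusted over the list alone; adjusted p = 7.19e-05; adjusted p = 0.531 with an estimated correlation). Of 26 immediate early genes 7 rose and 0 fell (adjusted p = 0.00988; adjusted p = 0.531 with an estimated correlation; adjusted p = 0.126 after the length and GC correction), including Dusp1 (1.52), Klf2 (1.35) and Btg2 (1.29). Of 28 NRF2 genes 6 rose (adjusted p = 0.042, 0.134 after the correction; camera, adjusted p = 0.619), Gstm1 by 1.14 (SE 0.244, adjusted p = 0.00741), again in a list emphasised by the study and not independent evidence.

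Of the lists above, collagens lost their test without TAC replicate 1 (adjusted p = 0.238) or 2 (0.418) and swim replicate 2 (0.336) or 3 (0.095). Resting fibroblast markers lost it without TAC replicate 1 (0.202) or 3 (0.395) and swim replicate 1 (0.132) or 3 (0.0584). Immediate early genes lost it without TAC replicate 1 (0.0548), 2 (0.159) or 3 (0.0648) and swim replicate 1 (0.0747) or 2 (0.156). NRF2 genes lost it without TAC replicate 1 (0.743) or 3 (0.218) and swim replicate 1 (0.0824), 2 (1.0) or 3 (0.0951). Acta2 and Col3a1 were called between 4 days of swimming and 3 days of TAC but lost the call with fewer libraries, at similar folds. Acta2 (-1.47, adjusted p = 0.0261) lost its call without TAC replicate 1 (-1.42, adjusted p = 0.104) or 2 (-1.41, adjusted p = 0.0794) and without swim replicate 2 (-1.28, adjusted p = 0.11) or 3 (-1.52, adjusted p = 0.0517). Col3a1 (-1.34, adjusted p = 0.0262) lost it without TAC replicate 1 (-1.33, adjusted p = 0.0947), 2 (-1.30, adjusted p = 0.0756) or 3 (-1.38, adjusted p = 0.0553) and without swim replicate 2 (-1.09, adjusted p = 0.12) or 3 (-1.29, adjusted p = 0.0683). Mt2 (-1.35, adjusted p = 0.0558), Mt1 (-0.51), Nqo1 (-0.03), Hmox1 (-1.04), Tcf21 (0.96), Pdgfra (0.49), Myh6 (-0.71), Tnnt2 (-0.16), Ptprc (0.20) and Pecam1 (-0.67) did not pass the test. The comparison called 490 genes higher and 345 lower (835 called; 995 in the authors' deposited table, 411 higher and 584 lower). Without TAC replicate 1 the count was 369, and without swim replicate 2 it was 539.

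TAC at 10 days was compared with TAC at 3 days to follow pressure overload over time. Late matrix genes and vascular genes were higher at 10 days. Eln rose by 2.75 (SE 0.323, adjusted p = 7.11e-05), from 13.2 ± 1.97 FPKM (SD, n = 3) to 94.6 ± 13.8 (n = 3), Fmod, fibromodulin (chromosome 1, 134037515 to 134048277), by 2.54 (SE 0.213, adjusted p = 4.33e-06). Mfap4 rose by 2.33 (SE 0.251, adjusted p = 3.02e-05) and Postn by 1.73 (SE 0.358, adjusted p = 0.00688), from 15.6 ± 2.69 to 54.7 ± 12.8 FPKM. Cdh5 rose by 1.98 (SE 0.295, adjusted p = 0.000614), and the Notch targets Hey1 and Heyl by 1.88 (SE 0.272, adjusted p = 0.000472) and 1.23. Of 20 endothelial markers 12 rose and 0 fell (18 adjusted over the list alone; Fisher's exact test, adjusted p = 8.73e-10; adjusted p = 0.206 with an estimated correlation). Of 18 collagens 8 rose (14 adjusted over the list alone; adjusted p = 2.95e-05; adjusted p = 0.196 with an estimated correlation). Of 28 other matrix proteins 8 rose (14 adjusted over the list alone; adjusted p = 0.000852; adjusted p = 0.238 with an estimated correlation). Of 12 pericyte and smooth muscle markers 4 rose (adjusted p = 0.0126; adjusted p = 0.151 with an estimated correlation), a result lost without TAC 10 day replicate 2 (2 rose, adjusted p = 0.218) or 3 (3 rose, adjusted p = 0.0678).

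Metallothionein and chemokine genes were lower at 10 than at 3 days of TAC. Saa3 (chromosome 7, 46711998 to 46715676) had a log2 fold change of -3.77 (SE 0.494, adjusted p = 0.000374), Mt2 one of -3.52 (SE 0.419, adjusted p = 9.93e-05; 45.7 ± 8.87 FPKM against 545 ± 169), Spp1 one of -3.32 (SE 0.395, adjusted p = 9.96e-05). Mmp3, stromelysin, had one of -2.91 (SE 0.259, adjusted p = 4.39e-06), Timp1 one of -2.29 (SE 0.449, adjusted p = 0.00563) and Mt1 one of -2.08 (SE 0.24, adjusted p = 6.09e-05; 66.5 ± 13.4 against 282 ± 39.2 FPKM). All 3 metallothioneins fell (Fisher's exact test, adjusted p = 0.000411; adjusted p = 0.151 with an estimated correlation) and 4 of 28 NRF2 genes fell while 1 rose (adjusted p = 0.0326; adjusted p = 0.33 with an estimated correlation; adjusted p = 0.388 after the length and GC correction), lists that the study chose on these samples and that are not independent evidence. Of 26 chemokines and cytokines 5 fell (14 adjusted over the list alone; adjusted p = 0.00546; adjusted p = 0.287 with an estimated correlation), with Ccl7 at -2.21 and Ccl11 at -2.06. The chemokine list was lost without TAC 3 day replicate 1 (adjusted p = 0.182) and TAC 10 day replicate 2 (0.24) or 3 (0.258). The NRF2 list was lost without TAC 3 day replicate 2 (1.0) or 3 (1.0) and TAC 10 day replicate 2 (0.891) or 3 (0.888). Col1a1 (0.64), Col3a1 (0.93), Acta2 (0.09), Hmox1 (-1.69), Nqo1 (0.24), Tcf21 (-0.37), Pdgfra (-0.02), Myh6 (1.16), Tnnt2 (0.87), Ptprc (-0.21) and Pecam1 (1.10) did not pass. The test called 417 genes higher and 205 lower (622 called, 1598 in the authors' deposited table), against 297 without TAC 3 day replicate 1, 390 without TAC 3 day replicate 3 and 351 without TAC 10 day replicate 2.

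Swimming for 10 days was compared with swimming for 4 days to follow exercise over time. The linker histone gene Hist1h1c had a log2 fold change of -2.51 (SE 0.357, adjusted p = 0.00375; 9.68 ± 2.87 FPKM, SD, n = 3, against 60.7 ± 19.6, n = 3) at 10 days and Hist1h1b one of -2.02 (SE 0.282, adjusted p = 0.00375). Ifi27l2a (-1.72, SE 0.279, adjusted p = 0.0118) lost its call without 4 day replicate 1 (-1.65, adjusted p = 0.0576) or 2 (-1.68, adjusted p = 0.0672), without 10 day replicate 1 (-1.61, adjusted p = 0.118) or 3 (-1.71, adjusted p = 0.0658), and after the correction for length and GC content (-1.33, adjusted p = 0.0762). Mt2 was at 1.36 (adjusted p = 0.14), Mt1 at 0.70 (adjusted p = 0.146), Hmox1 at 1.42 (adjusted p = 0.197), Pecam1 at 0.98 (adjusted p = 0.156) and Postn at 0.84 (adjusted p = 0.183). Nqo1, Col1a1, Col3a1, Acta2, Timp1, Tcf21, Pdgfra, Myh6, Tnnt2 and Ptprc were between -0.46 and 0.53, with no call. With limma 1 gene rose and 29 fell (30 called), 2251 had an unadjusted p under 0.05, and the authors' deposited table called 695 (484 higher, 211 lower). A fit on the 6 compared libraries only called 0 genes, the length and GC correction left 9, and a threshold of 0.01 left 5. The count was 8, 6 and 121 without 4 day replicate 1, 2 and 3, and 5, 23 and 6 without 10 day replicate 1, 2 and 3. No list had a member called in excess. Adjusted over the list alone all 3 metallothioneins were higher (camera, adjusted p = 0.0261; adjusted p = 0.819 with an estimated correlation), a list that is not independent evidence here.

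Sedentary cardiomyocytes were compared with sedentary fibroblasts to describe the starting difference between the cell preparations. Cardiomyocytes had more of the contractile and oxidative genes. Myl2, the ventricular myosin light chain (chromosome 5, 122100980 to 122106854), was 7.92 log2 units higher (SE 0.651, adjusted p = 7.36e-09; 6393 ± 1371 FPKM, SD, n = 3, against 36.2 ± 33.1, n = 3). Tnnt2 (chromosome 1, 135836334 to 135852268) was 7.03 higher (SE 0.481, adjusted p = 2.14e-10; 771 ± 93.1 against 5.81 ± 4.12 FPKM). Mb, myoglobin, was 7.04 higher (SE 0.677), Fabp3, a fatty acid carrier, 7.04 (SE 0.558, adjusted p = 2.82e-09) and Myh6 5.51 (SE 0.515, adjusted p = 2.67e-08). All 22 cardiomyocyte markers (Fisher's exact test, adjusted p = 1.08e-07; adjusted p = 0.309 with an estimated correlation), all 32 oxidative phosphorylation genes (adjusted p = 1.03e-10; adjusted p = 0.275 with an estimated correlation) and 19 of 24 fatty acid oxidation genes (4 lower; adjusted p = 0.000965; adjusted p = 0.275 with an estimated correlation) were higher. Fibroblasts had more of the matrix and inflammatory genes. Dcn, decorin, was at -3.52 (SE 0.306; 75.5 ± 25.6 against 841 ± 116 FPKM), Col1a1 at -3.13 (SE 0.328, adjusted p = 3.97e-08), Tcf21 at -3.10 (SE 0.377, adjusted p = 3.83e-07), Pdgfra at -2.64 (SE 0.25, adjusted p = 8.87e-09). Cxcl1 was at -7.10 (SE 0.794, adjusted p = 5.24e-07), Il6 at -6.12 and Hmox1 at -6.02 (SE 0.687, adjusted p = 5.34e-07). Lower in cardiomyocytes were 17 of 18 collagens (adjusted p = 4.18e-06; adjusted p = 0.288 with an estimated correlation), 21 of 22 resting fibroblast markers (adjusted p = 2.57e-07; adjusted p = 0.275 with an estimated correlation), 25 of 26 chemokines and cytokines (adjusted p = 1.11e-08; adjusted p = 0.275 with an estimated correlation). So were all 26 interferon-stimulated genes (adjusted p = 9e-10; adjusted p = 0.423 with an estimated correlation) and 22 of 24 macrophage and monocyte markers (adjusted p = 1.19e-07; adjusted p = 0.339 with an estimated correlation).

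Mt2 (-4.01), Mt1 (-1.17), Ptprc (-2.40), Postn (-2.09), Col3a1 (-2.71) and Timp1 (-3.04) were lower in cardiomyocytes, Acta2 (4.13) and Nqo1 (2.81) were higher, and Pecam1 was at -0.68 (adjusted p = 0.0878). In cardiomyocytes 4010 genes were higher and 4002 lower of 10371 tested (8012 called, 7850 in the authors' deposited table). Cardiomyocyte markers averaged 1.62 to 4.09 log2 units in fibroblast libraries. Tnnt2 ran from 4.81 ± 1.03 FPKM (n = 2) after MI to 13.9 ± 6.98 (n = 3) after 10 days of TAC.

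Responses to different conditions were compared over the 9425 genes tested in both. The 3 sedentary libraries are shared, so each covariance and correlation of fold changes stands beside the one simulated for shared controls alone. Shared counts stand beside those of independent calls, which ignore shared controls. Both leave out the division of the libraries, which could make TAC and swim groups alike. The 4 day and 10 day swim responses shared 2692 genes called higher and 1270 called lower, with 0 in opposite directions (1079, 337.5 and 1233 for independent calls; covariance 0.561, simulated 0.0308; correlation 0.938, simulated 0.498). After the length and GC correction they shared 1431 and 1130, with 0 opposite (0.904). The 10 day TAC and 10 day swim responses shared 2363 higher and 1110 lower genes, with 51 opposite (1094, 346.2 and 1259; covariance 0.48, simulated 0.0313; correlation 0.788, simulated 0.502). After the correction they shared 1231 and 939, with 48 opposite (0.703). For 10 day TAC and MI, on different sides of the first axis, 469 were shared higher and 120 lower, with 126 opposite (326.4, 59.58 and 312.7). The covariance was 0.199 (simulated 0.0285) and the correlation 0.395, not above the simulated 0.408. The corrected counts were 442, 329 and 81 (0.484). MI and 10 day swim shared 210 higher and 25 lower, with 201 opposite (252.2, 30.11 and 180.9; covariance 0.0359, simulated 0.0242; correlation 0.108, simulated 0.371); after the correction the counts were 130, 101 and 166 (0.141).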

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

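The tests of a difference between the TAC effects were chosen only after the results were seen; the comparison of swimming at 10 and 4 days was not. Swim effects differed between 10 and 4 days for 30 genes, a comparison in which the same sedentary controls cancel. A fit on the compared groups only called 0, the length and GC correction 9, a threshold of 0.01 gave 5, and leaving out a library gave 5 to 121.

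TAC effects, taken against sedentary at 10 days and against sham at 3 days, differed for 17 genes, 14 of them with a larger effect at 10 days and 3 with a smaller one. For Postn the difference between the TAC effects was 3.02 log2 units (SE 0.537, adjusted p = 0.0251). The controls of the TAC effects differ in operation: compared directly, Postn was 1.73 higher at 10 than at 3 days of TAC (adjusted p = 0.00688), and the rest is the difference of sham from sedentary (1.29, adjusted p = 0.418). The corresponding differences were -2.87 for Mt2 (adjusted p = 0.0897), -1.36 for Mt1 (adjusted p = 0.174), -1.79 for Timp1 (adjusted p = 0.386), 0.76 for Col1a1 (adjusted p = 0.598) and 1.11 for Col3a1 (adjusted p = 0.49), none of which passed.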

How the results depend on the processing

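Alternatives for the authors' deposited calls, length and GC content, no filter on low FPKM, pseudocount and median scaling of counts, the fit on compared groups only, and list tests without single libraries, were chosen after seeing the data. No alternative fit without a library turned the sign of a call; where values moved, the cause was not tested. In the order of the report, an absolute log2 fold change of at least 1 left 2308 genes for 3 day TAC against sham, 2483 for 10 day TAC, 434 for MI, 2440 for 4 day swim, 1031 for 10 day swim and 1 for sham. It left 659 for 10 day swim against TAC, 279 for 4 day swim against 3 day TAC, 214 for TAC over time and 4484 for cardiomyocytes. A threshold of 0.01 gave 531 for MI, 2672 for 10 day swim, 0 for sham, 952 for 10 day swim against TAC, 353 for 4 day swim against 3 day TAC, 264 for TAC over time and 5 for swimming over time. The authors' deposited calls numbered 1766 for MI, 252 for sham, 1598 for TAC over time and 695 for swimming over time. Benjamini-Hochberg within the comparison on the authors' p-values gave 20 for sham, 533 for 4 day swim against 3 day TAC, 1101 for TAC over time and 139 for swimming over time. Without a filter on low FPKM 1706 genes were called for MI, 13 for sham and 18 for swimming over time. A pseudocount of 0.1 gave 1 for sham and 8 for swimming over time, and median-centred scaling 0 and 17. Length and GC correction gave 2710 for 10 day swim, 0 for sham and 9 for swimming over time. A fit on the compared groups only gave 558 for MI, 0 for sham, 435 for 4 day swim against 3 day TAC and 0 for swimming over time. Leaving out a library at a time gave 253 to 1300 for MI, 0 to 142 for sham, 1027 to 2465 for 10 day swim against TAC, 369 to 723 for 4 day swim against 3 day TAC, 297 to 486 for TAC over time and 5 to 121 for swimming over time.

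Of 738 named gene values, 666 stayed the same with length and GC correction, 43 were weaker, 9 stronger, 13 moved and 3 reversed: Myl9 in 10 day swim (-0.139), and Hes1 (-0.205) and Rpl19 (-0.06) in cardiomyocytes. Median-centred scaling left 720 the same and a pseudocount of 0.1 left 721. The authors' deposited fold moved 188 and left 535, and their table with pooled controls moved 168 and left 311. Of 90 list results, 80 stayed the same with length and GC correction, 83 with median-centred scaling and 83 with the authors' calls. For 4 day swim against 3 day TAC the correction cost 4 lists their call, NRF2 (adjusted p = 0.134), immediate early (0.126), crosslinking (0.134) and DNA replication (0.601).

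With the replicate number as a block, cardiomyocytes against fibroblasts had 7354 genes called, against 7244 in the unblocked fit of the same 6 libraries. The profiles of libraries with the same label correlated at 0.243, 0.312 and 0.0558 (wt), and not every library correlated best with its own number, so the numbers were not used as pairs.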

Other observations

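Every test of the interferon and metallothionein patterns below, and the depth and library-making tests of the length pattern, were chosen only after the results were seen; the ribosomal and mitochondrial test and the splits were written before. Single clock genes were higher after 10 days of swimming than after 10 days of TAC. Hlf rose by 1.10 (SE 0.223, adjusted p = 0.00245) and Cry2 by 0.59 (SE 0.165, adjusted p = 0.0165). The clock and pericyte genes named here were chosen after their values were seen and were not refitted without single libraries. Of 13 clock genes 5 rose and 0 fell (Fisher's exact test, adjusted p = 0.0501; camera, adjusted p = 0.0426; adjusted p = 0.583 with an estimated correlation). Against sedentary fibroblasts Tef, a clock output gene, was 1.12 higher after 10 days of swimming (SE 0.233, adjusted p = 0.00109). The hour of sampling is not given in the sources used here.

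Neutrophil markers lay lower and pericyte genes higher at 10 than at 3 days of TAC. Lcn2, lipocalin 2, had a log2 fold change of -2.18 (SE 0.274, adjusted p = 0.000163), and adjusted over the list alone 7 of 7 neutrophil markers were lower (Fisher's exact test on the 3 called, adjusted p = 0.4; camera, adjusted p = 2.06e-06; adjusted p = 0.196 with an estimated correlation). The pericyte genes Notch3 and Mcam rose by 0.80 (SE 0.125, adjusted p = 0.000874) and 0.99 (SE 0.19, adjusted p = 0.00446).

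Short transcripts were higher and long ones lower in TAC and swim fibroblasts. Sequencing depth did not account for it: 11 of the 12 TAC and swim libraries lay within the depth range of the others, of which 3 lay within theirs, and the difference between the slopes was -0.39 (SE 0.042) with depth in the model and -0.372 (SE 0.0551) between the 14 libraries of like depth. Nor did ribosomal and mitochondrial genes, without which the correlation of fold change and length after 10 days of swimming was -0.611. A step of library making or RNA handling shared by these libraries could produce a gap such as the 0.201 between the slopes of the 2 sets, though the 4 day swim libraries alone spread over 0.226, and it cannot be told apart from a response of the cells. Whether TAC and swimming both change transcript lengths in the animal stays open.

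Interferon-stimulated genes were lower in TAC and swim fibroblasts. The length and GC trend did not account for it: 20 were called lower after correction in 10 day TAC. Nor did an even loss of macrophages, whose markers would then fall at least as much. Their corrected median in 10 day TAC was 0.1284 (median absolute deviation 0.665) against -1.73 for the list. In 3 day TAC, 4 and 10 day swim it was -0.323, 0.541 and 0.196, against -1.55, -1.83 and -1.33. A weaker handling response was not decided: 9 of 26 immediate early genes were called higher at 4 days of swimming (Fisher's exact test, adjusted p = 0.825) and 12 lower over the TAC comparisons (adjusted p = 1 and 0.724). Fewer lymphocytes (3 markers tested), loss of a leukocyte subset (Ptprc fell in each comparison) and changed interferon signalling in the animals stay open.

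Metallothionein and NRF2 genes were higher in 10 day swim than in 10 day TAC fibroblasts. The length and GC trend did not account for it: 18 were called higher after correction. A glucocorticoid response could raise metallothioneins, but the median of the other glucocorticoid-responsive genes was 0.0231, which does not decide it. The difference may lie on the TAC side only. The median of these genes in 10 day swim against sedentary, 0.919, does not decide it. They were picked with the same swim libraries, and sedentary lies across the library division. Of 14, 6 were called higher and 0 lower. Gsta1, Gsta2 and Gsta3 (1.98, 1.98 and 2.17) stayed higher after the length and GC correction (1.23, 1.23 and 1.70). Gsr was at -0.694. A protective response to exercise stays open, as no test here addressed it.

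Exchanging libraries between groups of 3 gives only 10 splits, so a share under 0.05 cannot be reached. In each case 1 split, the real one, had the highest count. The real and highest other counts were 6195 and 0 for 10 day TAC, 6079 and 0 for 4 day swim, 4107 and 0 for 10 day swim, and 8012 and 1 for cardiomyocytes. For 10 day swim against TAC they were 2279 and 0, for 4 day swim against 3 day TAC 835 and 0, for TAC over time 622 and 1, and for swimming over time 30 and 0.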
